A study of Mus musculus with 8 samples.

How the data were processed

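The series holds liver RNA from 4 floxed control and 4 hepatocyte *Smpd3* knockout samples, all on the HFMCD diet for 9 weeks, grouped and numbered by the sample titles. Libraries were made with a stranded total RNA kit, per the labels. The authors deposited 1 table of TPM values, transcript abundances scaled to each library's own total, for 55416 gene identifiers in 8 columns, rounded to 2 decimals. The submitters' processing notes name RSEM 1.3.3 and the build GRCh38.p13, which is a human build, while the identifiers are those of mouse genes. The aligner, the annotation release and the strand setting are not given in the sources used here. Because TPM is a share of each library, a change in a few abundant transcripts moves every other value, and depth is unknown, so no counting interval is given and no count test was run.

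Symbols were taken from a table that pairs mouse gene identifiers with names, and 52083 of the 55416 identifiers matched. Some identifiers were absent from the reference annotation, which is therefore not the one used by the authors, and no coordinates are printed. *Arntl* is the symbol in that table for the gene also called *Bmal1*.

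Values were transformed to log2(TPM + 1), with a pseudocount of 1, and genes with at least 1 TPM in at least 4 of the 8 libraries were tested, 12710 in all. The knockout was compared with the floxed control in limma 3.58.1 under R 4.3.3 (lmFit and eBayes with trend), without covariates, at a Benjamini-Hochberg adjusted p of 0.05. *Smpd3* was also tested by a 2-sided exact permutation test of the difference in mean log2 value. The 44 gene lists were fixed before the data were examined, as were the tests and settings other than those said to be chosen later. The lists were compared by limma's camera with a preset correlation of 0.01, adjusted over the lists with at least 5 tested members, and beside it with an estimated correlation and by fry. Counts of members past the threshold are given over all genes and adjusted over the list alone.

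The genes named were *Smpd3*, then up to 12 per direction with the largest fold change among genes past the threshold whose groups did not overlap and whose mean was at least 1 TPM. Where a direction had fewer than 8, it was filled to 8 with the genes of smallest unadjusted p, which are said not to pass. Up to 4 members of smallest p were taken from each list described. Genes with only a clone, predicted or identifier name are counted but not named, and some list members are counted but not reported here. Clock and other list members beyond these 4, and immunoglobulin constant genes, are named because they passed over the list alone or bear on a test.

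On simulated libraries drawn from the real means and spreads of the 12710 genes, with 100 genes changed 2-fold and 100 changed 4-fold, all above 10 TPM, the comparison of knockout with floxed control recovered 91.0% and 99.0% of them with 10 wrong calls. With no gene changed it made 0 calls and called 0 of 44 lists, and the simulated genes were independent of one another, unlike real ones. A larger number of changed genes eases the adjusted threshold, and the real comparison called 13 genes. The shares recovered therefore do not carry over to the real data. The alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, median-of-ratios scaling, rescaling without mitochondrially encoded genes and the 20 most abundant genes, quantile normalization, robust eBayes, library weights, the replicate number as a block, and leaving out each library in turn. A clock score, the first principal component of the clock list, was added as a covariate after the data were seen. The score did not overlap between the groups, so a fit with it hardly separates the score from the genotype.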

Results

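Gene expression was measured by RNA sequencing in 8 mouse liver libraries, 4 from floxed controls without the albumin-driven Cre recombinase and 4 from animals in which Cre removed *Smpd3* in hepatocytes. *Smpd3* encodes neutral sphingomyelinase 2, an enzyme that cleaves sphingomyelin to ceramide and phosphocholine. All animals received the HFMCD diet for 9 weeks, a diet used here to induce steatohepatitis. The comparison is therefore of knockout with control livers on that diet, without a group on another diet. The controls lacked Cre, so the presence of Cre and the loss of *Smpd3* cannot be told apart. The values were transcript abundances scaled to each library's total (TPM), which keep no record of sequencing depth, and each library summed to between 994563 and 995449 TPM. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these samples. Of 55416 listed genes, 12710 reached 1 TPM in at least 4 of the 8 libraries and were tested. Fold changes are knockout minus control on the log2(TPM + 1) scale, which understates the change of genes with low TPM.

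*Smpd3* (ENSMUSG00000031906) fell in the knockout livers. Its level was 9.58 ± 2.65 TPM in the floxed controls (SD, n = 4) and 1.88 ± 0.86 TPM in the knockouts (SD, n = 4), or 19.6% of the control mean. The controls ranged from 6.38 to 12.54 TPM and the knockouts from 1.17 to 3.03 TPM, so that the groups did not overlap. The log2 fold change was -1.89 ± 0.24 (SE), with a Benjamini-Hochberg adjusted p of 0.0300 in limma. A 2-sided exact permutation test of *Smpd3* gave p = 0.0286, the smallest that 70 assignments of 4 against 4 can give. The adjusted p rose above 0.05 without floxed control 1 (0.0874), floxed control 2 (0.0558), knockout 1 (0.0727), knockout 3 (0.0680) or knockout 4 (0.0505), and the log2 fold change stayed between -2.06 and -1.76.

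Which other genes differed between the genotypes was asked next. In limma, 13 of the 12710 genes passed an adjusted p of 0.05, 6 higher and 7 lower in the knockout, and in all 13 the groups did not overlap. Among the genes that rose, *Arntl* (ENSMUSG00000055116), which encodes the core clock activator BMAL1, went from 4.77 ± 1.44 to 14.3 ± 3.55 TPM (SD, n = 4 per group; log2 fold change 1.41 ± 0.21 SE). *Osgin1* (ENSMUSG00000074063), an oxidative stress response gene, went from 177 ± 16.4 to 368 ± 72.2 TPM (1.03 ± 0.13 SE). *Chka* (ENSMUSG00000024843), the choline kinase that starts phosphatidylcholine synthesis from choline, went from 36.0 ± 4.01 to 69.3 ± 10.3 TPM (0.92 ± 0.12 SE). *Pter* (ENSMUSG00000026730), which encodes a phosphotriesterase-related protein, went from 75.4 ± 5.14 to 130 ± 18.3 TPM (0.77 ± 0.10 SE). The crystallin gene *Crygn* (ENSMUSG00000038135) rose by 0.96 and *Hectd2os* (ENSMUSG00000087579), a transcript from the strand opposite *Hectd2*, by 0.88 on the log2 scale. The library kit was stranded, per the labels, but how the reads were assigned to strands is not given in the sources used here, so the value of *Hectd2os* is uncertain. To bring the named genes of this direction to 8, *Leap2* (log2 fold change 0.70, adjusted p = 0.0600) and *Coq8a* (0.56, adjusted p = 0.0780) were added, and neither passed. *Leap2* encodes a circulating liver peptide that blocks the ghrelin receptor, and *Coq8a* serves coenzyme Q synthesis.

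Beside *Smpd3*, the genes that fell included another gene of sphingolipid metabolism. *St3gal5* (ENSMUSG00000056091), which encodes the sialyltransferase that makes the ganglioside GM3 from lactosylceramide, went from 121 ± 21.1 to 46.5 ± 10.8 TPM (SD, n = 4 per group), or 38.5% of the control mean (log2 fold change -1.37 ± 0.18 SE, adjusted p = 0.0300 in limma). Its adjusted p rose above 0.05 without floxed control 1 (0.0874), floxed control 4 (0.0830), knockout 2 (0.0978) or knockout 3 (0.0622), while its log2 fold change stayed between -1.48 and -1.21 in the planned settings. *Slc37a4* (ENSMUSG00000032114), the glucose-6-phosphate transporter of the endoplasmic reticulum, went from 72.3 ± 2.77 to 45.4 ± 5.83 TPM (-0.67 ± 0.10 SE). *Rarres1* (ENSMUSG00000049404), a retinoic acid receptor responder gene, went from 94.3 ± 9.94 to 59.2 ± 4.35 TPM (-0.66 ± 0.10 SE). The other named genes were 2 immunoglobulin light chain variable segments. *Iglv3* (ENSMUSG00000076939) stood at 4.03, 3.86, 7.47 and 2.24 TPM in floxed controls 1 to 4, at 0.31 TPM in knockout 1, and was listed at 0 in the other knockouts. *Igkv3-4* (ENSMUSG00000096715) stood at 6.19, 5.32, 9.02 and 2.59 TPM in the controls and at 0.36, 0.41, 0 and 0.84 TPM in the knockouts. Variable segments resemble one another and share reads, so these values are uncertain. The last of the 7 genes carries only a clone name and is counted but not named. *Spata2l* was added to bring this direction to 8 and did not pass (log2 fold change -0.79, adjusted p = 0.0609).

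**Figure D1:**
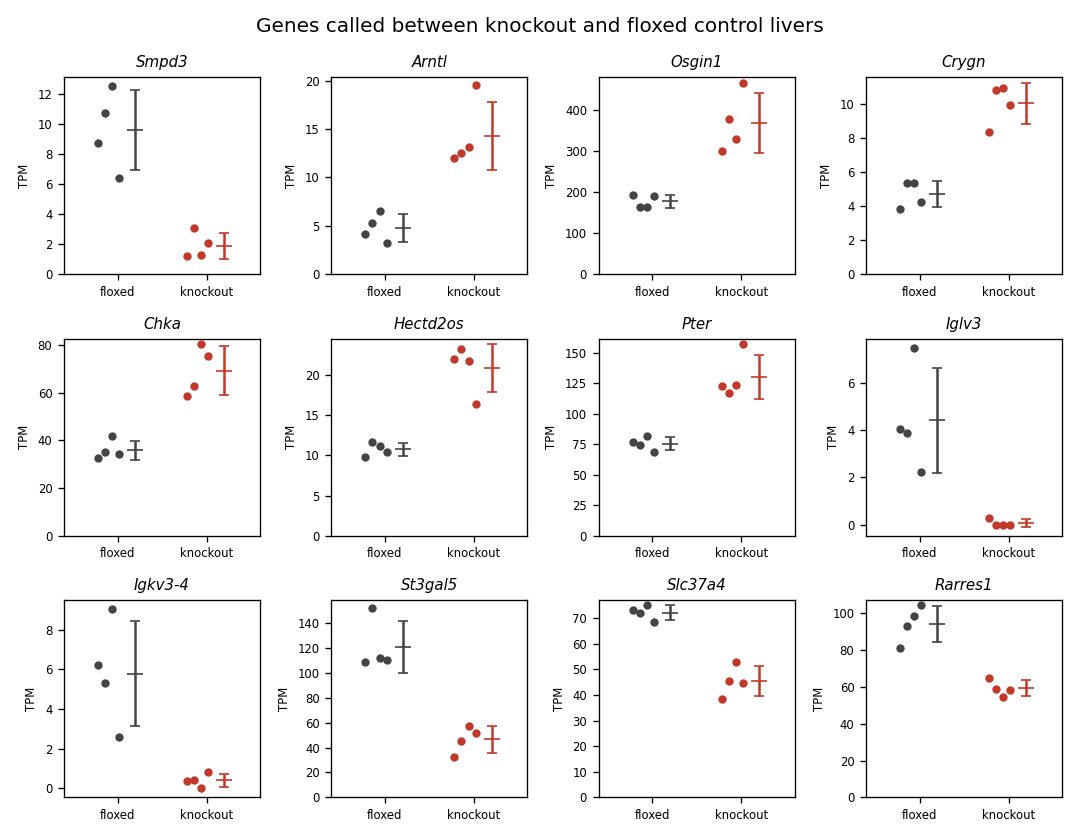
TPM (vertical axes, linear) of the 12 named genes that passed the threshold, in 4 floxed control libraries (grey points) and 4 knockout libraries (red points), with the mean and SD of each group beside the points. *Smpd3* lies between 1.17 and 3.03 TPM in the knockouts and between 6.38 and 12.54 TPM in the controls, and no gene shown has overlapping groups.

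The number of genes past the threshold depended on single libraries. It was 0 without floxed control 1 or knockout 3, 2 without knockout 2, 3 without floxed control 4 and 5 without knockout 1. All 13 genes kept their direction in each of the 8 fits that left a library out. That was fixed in advance, because their groups did not overlap. *Iglv3* kept its call in 5 of these 8 fits, *St3gal5* in 4, *Smpd3*, *Osgin1* and *Igkv3-4* in 3, *Chka* and *Pter* in 2, *Arntl* and *Hectd2os* in 1, and *Crygn*, *Slc37a4* and *Rarres1* in 0. At an unadjusted p under 0.05, 1019 genes passed where chance gives 636 on average, and 603 genes (4.74%) had groups that did not overlap, where chance gives 2.86% on average. Genes that vary together widen the spread of such counts, and that spread was not measured.

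Gene lists were then compared, each against the other genes in the camera test. The median log2 fold change of all tested genes was 0.05, so a list could point lower with a mean above 0. Of 44 lists, 13 passed in limma's camera test with a preset correlation between genes, 9 lower and 4 higher in the knockout. None passed with an estimated correlation, where the smallest adjusted p was 0.362, or by the directional p of fry, where it was 0.335. By fry's mixed p, which asks whether members change in either direction, 10 lists passed (smallest adjusted p 0.000239). Of the 13, these were the lipid droplet, hepatocyte, fatty acid oxidation and clock lists. The rest were the bile acid, insulin signalling, xenobiotic, oxidative stress, phospholipid and pericentral hepatocyte lists. Regrouping the same 8 libraries without regard to genotype gave at least as many lists by camera in 25 of 35 splits, the real split included. The values below therefore describe these libraries.

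The circadian clock genes went in opposite directions. Of 22 measured members, 6 were higher and 8 lower in the knockout when adjusted over the list alone, 8 did not pass, and 1 (*Arntl*) passed over all genes. The 4 members with the smallest p were *Arntl*, *Ciart*, *Npas2* and *Nfil3*. The clock repressor gene *Ciart* went from 2.96 ± 1.46 to 0.43 ± 0.09 TPM (SD, n = 4 per group), *Npas2*, a partner of BMAL1, from 0.81 ± 0.47 to 3.09 ± 0.90 TPM, and *Nfil3* from 12.3 ± 3.29 to 26.8 ± 6.81 TPM. The other members that passed over the list alone, named after their values were seen, included *Cry1* and *Rora*, which were higher, and *Dbp*, *Usp2*, *Tef*, *Nr1d1*, *Bhlhe40*, *Bhlhe41* and *Hlf*, which were lower. *Dbp*, a clock output gene, had a log2 fold change of -2.44 ± 0.46 (SE), and floxed control 3, at 5.43 TPM, lay closest to the knockouts. The camera test pointed lower for the list (median log2 fold change -0.40, adjusted p = 0.000744 by camera, adjusted p = 0.930 with an estimated correlation). Because members moved in opposite directions, this direction depends on how many of each kind were listed. The list's mean log2 fold change went from -0.25 to -0.15 without knockout 1, where the list still passed. The labels give no time of collection.

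**Figure D2:**
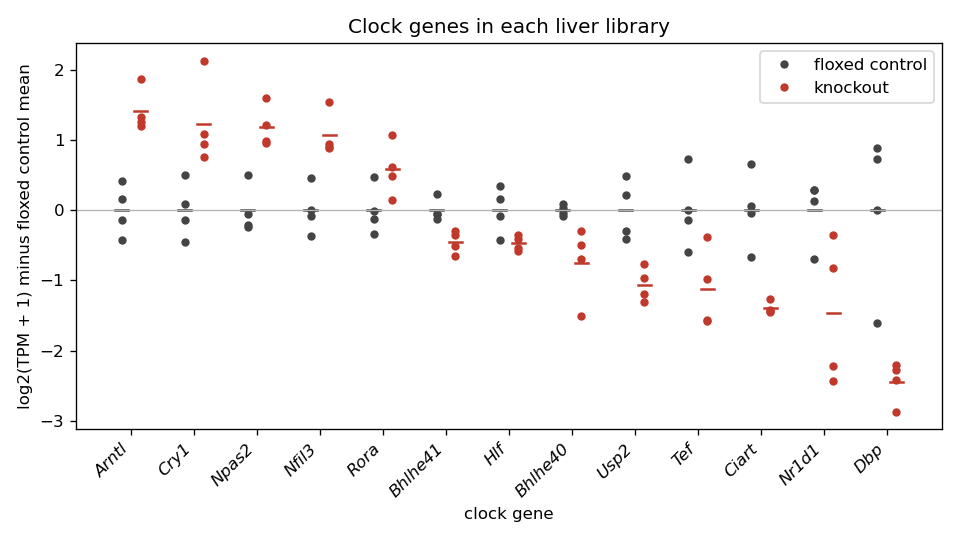
Difference from the floxed control mean in log2(TPM + 1) (vertical axis) for the 13 clock genes named in the text, all past the threshold when adjusted over the list alone (horizontal axis), with 1 point per library, floxed controls in grey, knockouts in red, and a line at each group mean. *Arntl* has the highest mean difference in the knockouts, 1.41, and *Dbp* the lowest, -2.44.

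Genes of lipid droplets were lower as a group. Of 17 lipid droplet genes, 14 had lower values in the knockout and 3 passed, all lower, when adjusted over the list alone. These were *Cidec*, a lipid droplet fusion gene (45.8 ± 5.57 to 27.1 ± 9.20 TPM; SD, n = 4 per group), *Pnpla2*, the adipose triglyceride lipase (85.3 ± 16.1 to 58.3 ± 8.94 TPM), and *Fitm2* (18.3 ± 2.61 to 13.2 ± 1.16 TPM). The list had a median of -0.15 and an adjusted p of 6.95e-06 by camera (adjusted p = 0.362 with an estimated correlation). Of 43 genes of fatty acid oxidation and PPAR alpha targets, 4 were lower and 1 higher when adjusted over the list alone, and 38 did not pass. *Cpt1a*, which carries fatty acids toward mitochondrial oxidation, went from 167 ± 26.3 to 119 ± 9.72 TPM, *Pex11a* from 56.3 ± 4.66 to 41.8 ± 2.18 TPM and *Eci2* from 159 ± 12.03 to 125 ± 7.62 TPM. The hormone gene *Fgf21* went the other way, from 38.2 ± 7.79 to 81.9 ± 32.8 TPM. The test pointed lower with a median and a mean of -0.02 (adjusted p = 0.000469 by camera, adjusted p = 0.930 with an estimated correlation). The mean was -0.07 after median-of-ratios scaling or quantile normalization. It was -0.04 after rescaling without mitochondrially encoded genes and the 20 most abundant genes, and the list passed in each. The mean turned to 0.03 without floxed control 1 and 0.01 without knockout 1. There the median of all tested genes rose from 0.05 to 0.09 and 0.10. The camera test still pointed lower and passed (adjusted p = 0.0191 and 0.00103). The mean was -0.05 without floxed control 3 or knockout 4, -0.04 without floxed control 4 and -0.01 without knockout 2. With a clock score as a covariate, added after the data were seen, the mean was 0.02 and the list did not pass (adjusted p = 0.298). The score did not overlap between the groups, so this fit hardly separates it from the genotype.

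Genes of the unfolded protein response were higher as a group. Of 33 members, 28 had higher values in the knockout, and 5 were higher and 1 lower when adjusted over the list alone. The chaperone gene *Calr* went from 504 ± 33.0 to 676 ± 89.0 TPM (SD, n = 4 per group), *Chac1* from 4.65 ± 2.77 to 17.2 ± 7.66 TPM and *Trib3* from 19.6 ± 7.36 to 42.1 ± 12.1 TPM. *Asns*, the asparagine synthetase gene, was the member that was lower, from 16.4 ± 1.59 to 10.2 ± 2.48 TPM. The median was 0.29, with an adjusted p of 2.73e-05 by camera (adjusted p = 0.930 with an estimated correlation). Knockout 1 had the lowest list mean of the 8 libraries, -0.26, and knockout 4 the highest, 0.51, as deviations from the mean of all libraries on the log2 scale. The list's mean log2 fold change went from 0.30 to 0.18 without knockout 4, where it still passed (adjusted p = 0.00217).

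The camera test pointed lower for the lists of hepatocyte, periportal and male-biased genes, with lower values in 21 of 33, 18 of 29 and 16 of 21 members. Of 33 hepatocyte markers, *Arg1* (744 ± 48.6 to 563 ± 67.9 TPM; SD, n = 4 per group) and *Apoa1* (14504 ± 1748 to 10905 ± 879 TPM) passed when adjusted over the list alone, and the list's median was -0.03 (adjusted p = 0.000676 by camera, adjusted p = 0.930 with an estimated correlation). Of 29 periportal genes, *Arg1* and *Serpina1e* passed over the list alone (median -0.08, adjusted p = 0.00293, adjusted p = 0.930 with an estimated correlation). Of 21 male-biased genes, *Cyp2d9* (353 ± 12.5 to 245 ± 26.7 TPM), *Mup1* (248 ± 97.2 to 94.1 ± 19.7 TPM) and *Serpina1e* (2047 ± 793 to 797 ± 410 TPM) passed over the list alone, all lower (median -0.18, mean -0.36, adjusted p = 2.52e-05, adjusted p = 0.930 with an estimated correlation). Members of the *Mup* and *Serpina1* families are close copies, so reads assigned to one of them are uncertain. The mean log2 fold changes of the hepatocyte and periportal lists were -0.08 and -0.09. Without floxed control 4 these were -0.07 and -0.10 but the lists no longer passed (adjusted p = 0.142 and 0.116), nor did they after quantile normalization (-0.08 and -0.13, adjusted p = 0.0881 and 0.0554) or without knockout 2 (-0.05 and -0.03, adjusted p = 0.108 and 0.548). After median-of-ratios scaling the means were -0.14 and -0.15 and both passed (adjusted p = 0.00316 and 0.0144), as did the periportal list without knockout 4 (-0.15, adjusted p = 5.84e-05).

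Markers of cells other than hepatocytes moved with 1 control library, which also stood apart in general measures. Floxed control 4 had 12115 genes at 1 TPM or more, against 12678 to 12871 in the other controls, and the largest shares of TPM of all libraries in its 20 most abundant genes (33.6%) and in mitochondrially encoded genes (8.92%). It was the lowest control in 10 of 10 lists of markers of other cells and matrix and in 20 of the 34 other lists. Its liver endothelial list mean was -0.57, against 0.25 to 0.41 in the other controls and -0.35 to 0.01 in the knockouts. The endothelial list was lower in the knockout (21 of 25 members lower, none past the threshold over the list alone; adjusted p = 2.40e-05 by camera, adjusted p = 0.930 with an estimated correlation). Its mean log2 fold change of -0.23 became -0.46 without floxed control 4, -0.13 without floxed control 2 and -0.15 without floxed control 1 or knockout 1, and it passed in each. *Lyve1*, a gene of sinusoidal endothelium, stood at 4.83 ± 1.93 TPM in the controls and 2.18 ± 0.46 TPM in the knockouts (SD, n = 4 per group; adjusted p = 0.397). In the Kupffer cell list the scavenger receptor gene *Marco* (17.9 ± 1.52 to 9.62 ± 1.73 TPM) was lower and the only one of 18 members past the threshold over the list alone. The Kupffer list had an adjusted p of 0.00535 by camera (adjusted p = 0.930 with an estimated correlation), with a mean log2 fold change of -0.13. The mean was -0.31 without floxed control 4, -0.21 without knockout 4 and -0.08 without floxed control 2. It was close to 0 without floxed control 3 (-0.04, adjusted p = 0.183) or knockout 1 (-0.0095, adjusted p = 0.0581), where the list did not pass.

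Antigen presentation, interferon-stimulated and T and NK cell genes were higher as groups, with no member past the threshold over any of these lists alone. Higher values were seen in 16 of 17, 41 of 43 and 16 of 17 members, and the medians were 0.14, 0.15 and 0.29. The adjusted p was 0.0154, 0.0156 and 0.0312 by camera, and with an estimated correlation the adjusted p was 0.930, 0.985 and 0.930. *H2-Aa*, a class II antigen presentation gene, stood at 165 ± 56.3 TPM in the controls and 221 ± 12.1 TPM in the knockouts (SD, n = 4 per group). Floxed control 4 had the lowest mean of all libraries in each of these lists, and without it the mean log2 fold changes went from 0.21, 0.18 and 0.32 to 0.06, 0.07 and 0.22 and none passed (adjusted p = 0.142, 0.130 and 0.0515). With the clock covariate the means turned to -0.27, -0.42 and -0.08, and the first 2 lists passed as lower (adjusted p = 0.00287, 4.03e-10 and 0.275). That fit hardly separates the clock score from the genotype, so these turns cannot be read as effects of the knockout. Antigen presentation also did not pass without floxed control 2 (mean 0.21, adjusted p = 0.0979). The interferon-stimulated list did not pass without floxed control 1 (mean 0.20, adjusted p = 0.0771), floxed control 2 (0.12, 0.571) or knockout 1 (0.23, 0.0507). The T and NK cell list did not pass without floxed control 1 (mean 0.30, adjusted p = 0.245), floxed control 2 (0.28, 0.203) or knockout 3 (0.19, 0.280). Without floxed control 3 the means of the first 2 lists were 0.32 and 0.33. With library weights none of the 3 lists passed (means 0.12, 0.10 and 0.29, adjusted p = 0.190, 0.306 and 0.0796). The mitochondrially encoded genes were lower with all libraries (median -0.07, adjusted p = 0.0269 by camera, adjusted p = 0.930 with an estimated correlation). They were not lower without floxed control 4 (mean log2 fold change 0.01, adjusted p = 0.762) or without knockout 4 (0.01, 0.380). Their mean was -0.06 without knockout 2, against -0.05 with all libraries, but the list did not pass (adjusted p = 0.121). It also did not pass without a filter (mean -0.05, adjusted p = 0.0711), after median-of-ratios scaling (-0.11, 0.162) or quantile normalization (-0.04, 0.536), or with library weights (-0.0031, 0.290). It passed with means of -0.03 without floxed control 1, -0.09 without floxed control 2 or 3, and -0.11 without knockout 3. These genes share reads with nuclear copies, and their values are uncertain.

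**Figure D3:**
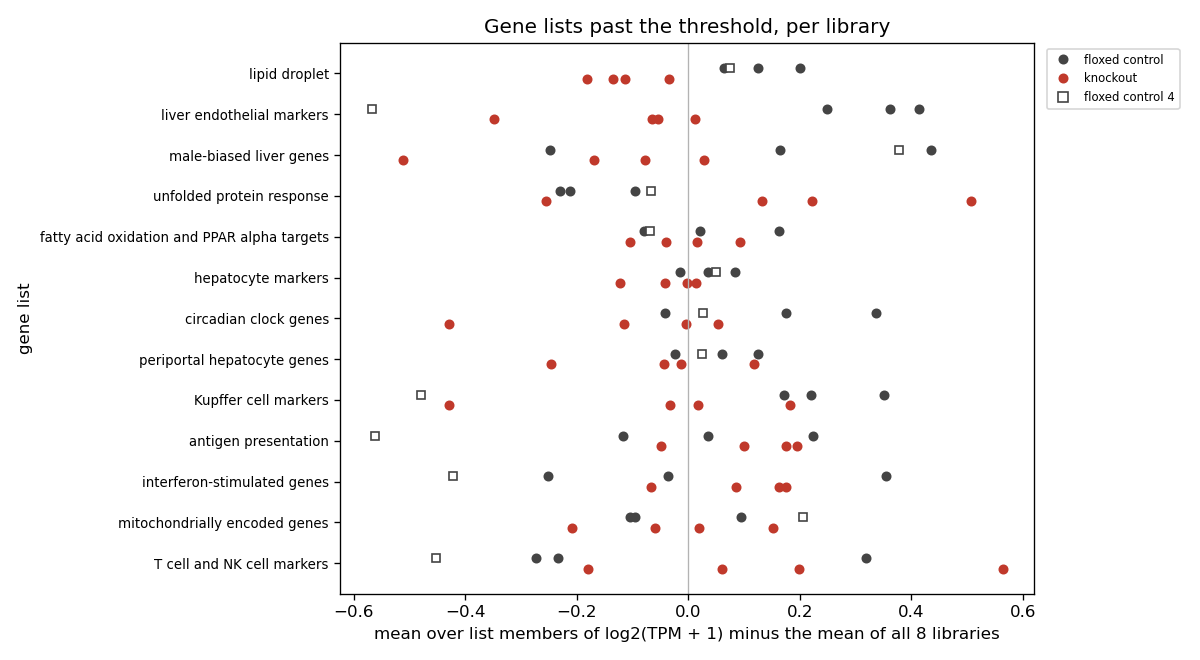
Mean over each list's members of log2(TPM + 1) minus the mean of all 8 libraries (horizontal axis) for the 13 lists past the camera threshold (vertical axis), with 1 point per library. Floxed control 4, drawn as an open square, lies at -0.57 for the endothelial list, and the lipid droplet list has its 4 knockout points below its 4 control points.

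The lists closest to the known action of *Smpd3* did not pass. Of 41 sphingolipid genes other than *Smpd3*, *St3gal5* alone passed, over all genes and over the list alone, and the list had an adjusted p of 0.596, with a median of 0.02 and a mean of 0.02 above 0 while the test pointed lower, and the mean ran from -0.09 without floxed control 4 (adjusted p = 0.130) to 0.09 without floxed control 2. *Sgms2*, a sphingomyelin synthase gene, stood at 9.23 ± 1.80 TPM in the controls and 12.2 ± 1.97 TPM in the knockouts (SD, n = 4 per group; adjusted p = 0.606). None of 24 genes of extracellular vesicle machinery passed over the list alone (adjusted p = 0.806 for the list), nor did any of 24 genes of fatty acid synthesis (adjusted p = 0.958, with a median of 0.07 and a mean of 0.04, or -0.01 to 0.14 with 1 library left out, while the test pointed lower), 24 of cholesterol synthesis (0.156), 41 of fibrosis and extracellular matrix (0.864) or 33 cytokines and chemokines (0.338). The cholesterol synthesis list passed, higher, without floxed control 1 (adjusted p = 0.000925) or knockout 1 (0.00659), where its mean log2 fold change went from 0.14 to 0.25, and the fibrosis list without knockout 3 (0.0134, from 0.11 to 0.21). Without floxed control 4 neither passed, with means of 0.06 for cholesterol synthesis and -0.07 for fibrosis (adjusted p = 0.293 and 0.112).

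Among genes of metabolism and defence, single members passed over lists that did not pass by camera. By fry's mixed p these lists passed (adjusted p = 0.00187 for xenobiotic, 0.00382 for oxidative stress and 0.0117 for phospholipid genes). Of 39 xenobiotic genes, *Cyp2c38*, *Cyp2c29*, *Cyp3a11* and *Cyp2a4* were higher and *Cyp2d9* lower when adjusted over the list alone (adjusted p = 0.0764 for the list). The xenobiotic list passed, higher, without a filter (0.00735), with library weights (0.0396), and without floxed control 2 (0.0358), floxed control 4 (0.0229), knockout 2 (0.0268) or knockout 4 (0.0345), with means between 0.14 and 0.20 against 0.16. It did not pass with an estimated correlation (adjusted p = 0.930) or after median-of-ratios scaling (mean 0.11, adjusted p = 0.117 by camera). With the clock covariate its mean was 0.40 (adjusted p = 8.21e-06 by camera). *Cyp2c29* went from 19.6 ± 3.90 to 44.4 ± 12.4 TPM (SD, n = 4 per group). Of 38 genes of oxidative stress and NRF2 targets, *Osgin1*, *Gclc*, *Gstm3*, *Gsta3* and *Gsta4* were higher, and the metallothionein genes *Mt1* (946 ± 254 to 338 ± 122 TPM) and *Mt2* (560 ± 202 to 190 ± 54.7 TPM) lower, over the list alone (adjusted p = 0.287 for the list). Of 32 genes of phospholipid and methionine metabolism, members higher over the list alone included *Chka* and *Cbs* (adjusted p = 0.307 for the list, and 0.0268 without knockout 2). The mean of this list was 0.11, or 0.12 without knockout 2 and 0.04 without floxed control 4. Several of the *Cyp2c*, *Gsta* and *Gstm* genes are close copies of one another and uncertain for that reason.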

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

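The tests of collection phase, genotype and clock, antibody-secreting cells, and cell content of floxed control 4 were chosen after the results were seen. A library was set apart where its gap to the nearest of its group, divided by the group's range, exceeded Dixon's critical value. This held for 22 of 334 groups of values, where chance gives 16.7.

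Among clock genes, knockout 4 stood above the other knockouts in *Arntl* (19.55 against 11.95 to 13.1 TPM, gap share 0.849), *Nfil3* (36.99 against 22.97 to 23.98 TPM, 0.928) and *Cry1* (13.54 against 4.6 to 6.02 TPM, 0.841), and knockout 2 in *Ciart* (0.56 against 0.37 to 0.4 TPM, 0.842). The clock genes moved in opposite arms between the genotypes. All 14 clock genes that passed over the list alone still passed in the same direction after median-of-ratios scaling. That scaling moved the median log2 fold change of all tested genes only from 0.0543 to 0.00355, so this outcome was close to fixed in advance. A scaling moves all genes of a library the same way, so the opposite directions argue against it as the cause. All 18 tested clock genes of known phase went with a single shift, 12 of them past the threshold over the list alone, but their phases were assigned after the values were seen. Another phase of the daily cycle at collection and an effect of the genotype on the clock cannot be told apart, because the labels give no collection time, and the gap of 1.24 between the groups in the clock score arises either way.

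*Iglv3* was listed above 0 in knockout 1 alone of the knockouts (0.31 TPM, gap share 1). With the other knockouts at 0, any value above 0 gives that share. *Iglv3* and *Igkv3-4* were lower in the knockout, and of 74 tested variable segments 59 were lower (median log2 fold change -0.37). Fewer antibody-secreting cells would lower the constant-region genes alike. The median log2 fold change of *Igkc*, *Igha*, *Iglc2* and *Jchain* was -0.39 (the largest SE of the 4 was 0.30), against -2.21 for *Igkv3-4*. *Ighg2c*, not among the 4, stood at -0.88 ± 0.33 (SE). *Ighm*, also not among them, went the other way, at 0.48 ± 0.15 (SE). The B cell and plasma cell list had 7 members higher and 6 lower (adjusted p = 0.307 by camera). Reads assigned to related segments instead would raise those, and the other *Iglv* and *Igkv3* segments together changed by -6.99 ± 5.80 TPM (SE), while *Iglv3* and *Igkv3-4* lost 9.70 TPM. Fewer such cells stay open for the smaller difference over all segments, and for *Iglv3* and *Igkv3-4* a different antibody repertoire in the animals of each group may remain, on which no test here bears.

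Floxed control 4 stood below the other controls in the endothelial list (-0.57 against 0.25 to 0.41, gap share 0.832), the cytokine and chemokine list (-0.46 against 0.05 to 0.12, 0.871) and *Relb* (6.64 against 8.81 to 9 TPM, 0.919), and above them in *mt-Nd6* (1937.92 against 1490.15 to 1541.5 TPM, 0.885) and *Cyp2c40* (3.9 against 1.58 to 1.96 TPM, 0.836). It was the lowest control in 10 of 10 lists of markers of other cells and of matrix, but also in 20 of the 34 other lists, and it had the fewest genes at 1 TPM or more (12115). Fewer cells other than hepatocytes in that library therefore cannot be told apart from a broader difference of the library. A bias with transcript length stays open, since a correction for length kept 64.5% of the markers' mean deviation (-0.65 before, -0.42 after). No biological explanation beyond the cell content was tested.

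*St3gal5* was higher in floxed control 2 (152.25 against 108.83 to 111.73 TPM, gap share 0.933). Floxed control 2 was also above the other controls in *Igfbp1* (594.59 against 41.76 to 61.34 TPM, 0.965) and *Irs2* (9.79 against 2.45 to 3.19 TPM, 0.899). Floxed control 1 was higher in *Cyp51* (51.08 against 32.49 to 35.28 TPM, 0.850) and *Eln* (10.81 against 5.54 to 6.42 TPM, 0.833). Knockout 3 was higher in *Cyp2c38* (29.15 against 21.04 to 21.95 TPM, 0.888), *Cyp2b9* (64.07 against 27.37 to 29.65 TPM, 0.938) and *Sult2a2* (7.56 against 3.31 to 3.92 TPM, 0.856). Knockout 4 was higher in *Elovl3* (23.22 against 16.41 to 16.99 TPM, 0.915) and *Cyp2a4* (16.02 against 9.09 to 9.66 TPM, 0.918). Knockout 1 was higher in *Igfbp2* (1411.07 against 940.42 to 1011.94 TPM, 0.848) and lower in the cholesterol synthesis list (-0.25 against 0.16 to 0.20, 0.915).

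Of the 35 splits of the 8 libraries into 4 and 4, the real one alone called as many as 13 genes. The highest of the others called 2. The count therefore argues against chance, at 1 of 35 splits, the smallest share that 35 splits can give. It does not separate the genotype from a collection time or feeding state that a group may share, and *Smpd3* itself is among the 13. For gene lists chance stays open: 25 of the 35 splits called as many as the real 13, and the highest of the others called 21. The estimated correlations between the genes of the 13 lists, 0.0705 to 0.771, lie above the preset 0.01.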

How the results depend on the processing

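The clock score covariate was chosen after seeing the data. The score ran from -3.29 to -0.07 in the floxed controls and from 1.17 to 3.61 in the knockouts, without overlap. A fit with it hardly separates the score from the genotype, and the SE of *Smpd3* rose from 0.24 to 0.54. The values with this covariate therefore cannot be read as effects of the knockout. The 13 called genes, 6 higher and 7 lower, became 8 (4 lower) with a pseudocount of 0.1, 6 (3 higher, 3 lower) with a pseudocount of 5, 20 (10 higher) after rescaling without abundant genes and 20 (10 higher) with library weights, and 10 were higher after quantile normalization. They became 0, with 0 higher and 0 lower, without a filter, where 26719 genes were tested and 1539 had an unadjusted p under 0.05 in limma, and with the clock covariate (420 under 0.05). Leaving out 1 library gave 0 to 16 called genes, 0 to 9 higher and 0 to 7 lower, in part because fewer libraries were compared. All 13 genes kept their sign in every setting that tested them. For fits that left out a library or changed the pseudocount this was fixed in advance, because their groups did not overlap.

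*Smpd3* lost its call, with a log2 fold change of -1.89, without a filter (adjusted p = 0.167), and of -2.33 with the clock covariate (adjusted p = 1.00), over a range of 0.0134 to 0.167 in the planned settings, and left-out libraries gave -2.06 to -1.76. With a pseudocount of 5 it passed at -1.07 (adjusted p = 0.0384). With pseudocounts of 0.1 and 5, *Iglv3* stood at -4.86 and -0.86 and *Igkv3-4* at -3.80 and -0.96. No pairing by replicate number was seen: the correlations of deviations were -0.15, 0.03, -0.15 and -0.20, and 0 of 4 controls correlated best with the knockout of its number. These values are too few to exclude a pairing. With the replicate number as a block, 0 genes were called, 0 higher and 0 lower (743 at an unadjusted p under 0.05), and *Smpd3* stood at -1.89 (adjusted p = 0.0818).

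The 13 gene lists became 0 by camera with an estimated correlation and 0 by fry's directional p (10 of 44 lists passed by its mixed p), and 10 to 16 in the other planned settings. The mitochondrially encoded list turned to a mean of 0.0108 without floxed control 4, over a range of -0.108 to 0.0120 with 1 library left out. With the clock covariate these lists turned direction, with mean log2 fold changes of 0.31 (mitochondrially encoded), -0.42 (interferon-stimulated), -0.27 (antigen presentation), -0.0400 (acute phase and complement), -0.22 (fibrosis), -0.20 (stellate cell), -0.32 (recruited macrophage), -0.0781 (T and NK cell) and 0.0524 (clock, as the score is made from it). The fatty acid oxidation and hepatocyte lists lost their calls with it (adjusted p = 0.298 and 0.175), and the mean of the former went from -0.0175 to 0.0211, while the means of the endothelial, male-biased, Kupffer and periportal lists grew to -0.46, -0.65, -0.55 and -0.19. With a pseudocount of 5 the means of the endothelial, clock, and T and NK cell lists shrank to -0.15, -0.16 and 0.15, and the lists still passed. Except where fewer genes or libraries were compared, the cause was not tested. Depth is unknown, so what it limits cannot be given.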

Other observations

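Genes of bile acid handling held several members that passed when adjusted over the list alone, though the list did not pass by camera (adjusted p = 0.596). It passed by fry's mixed p, for changes in either direction (adjusted p = 0.000239). Of 29 members, 6 were higher and 1 lower in the knockout. *Abcb11*, the bile salt export pump gene, went from 119 ± 13.04 to 169 ± 11.0 TPM (SD, n = 4 per group), *Nr0b2*, which encodes the bile acid induced repressor SHP, from 40.6 ± 10.8 to 71.0 ± 12.5 TPM, and *Cyp2c70* from 180 ± 9.87 to 248 ± 33.9 TPM. *Cyp8b1*, a sterol hydroxylase gene, was the lower member, from 182 ± 27.4 to 132 ± 19.1 TPM. The female-biased liver genes had 11 of 12 members at higher values, with *Cyp2a4* past the threshold over the list alone. The list had an adjusted p of 0.0556 by camera and 0.930 with an estimated correlation. Its mean log2 fold change was 0.21 with a pseudocount of 5 (adjusted p = 0.0706 by camera) and 0.79 with the clock covariate. The female-biased list passed in 4 of 10 alternatives with all libraries, namely a pseudocount of 0.1 (adjusted p = 0.0483), no filter (0.0372), median-of-ratios scaling (0.0499) and the replicate block (0.0116), and without floxed control 2 (0.00832), floxed control 4 (0.0353), knockout 2 (0.0181) or knockout 4 (0.0345), over a range of 0.00832 to 0.370, with a mean log2 fold change of 0.38 that lay between 0.28 and 0.48 with 1 library left out.

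In the list of insulin, growth hormone and IGF signalling, 4 of 28 members were higher and 3 lower over the list alone. The list had an adjusted p of 0.0945 by camera, and 0.0169 without floxed control 3. By fry's mixed p, for changes in either direction, it passed (adjusted p = 0.000562). The median was -0.04 and the mean 0.11 while camera pointed lower. The mean was 0.03 without floxed control 3 and 0.20 without floxed control 2. *Igfbp1*, a gene that insulin represses, stood at 461.91 to 541.2 TPM in the knockouts and at 41.76 to 61.34 TPM in the controls other than floxed control 2, at 594.59 TPM. *Irs2*, also repressed by insulin, stood at 7.63 to 10.48 TPM in the knockouts, 9.79 TPM in floxed control 2 and 2.45 to 3.19 TPM in the other controls. Neither passed over all genes (adjusted p = 0.293 and 0.343 in limma), and without floxed control 2 both did (*Igfbp1* 3.21, adjusted p = 1.12e-05; *Irs2* 1.42, adjusted p = 0.0185; over all alternatives that left out another library neither passed). Floxed control 2 was the control set apart in both genes, so the passes without it were close to fixed in advance. Feeding state at collection is not given in the labels.

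Several genes of small p lie on chromosome 8, which also holds *Smpd3*, and a test chosen after this was seen asked whether that chromosome holds more than chance gives. Of 68 genes with an unadjusted p under 0.001, 7 lie there, *Smpd3* among them, where 3.74 are expected (Fisher's exact test, 2-sided, adjusted p = 0.603 over 20 chromosomes), so these genes are too few to decide it. Chromosomes 19 (6 where 2.52 are expected) and 10 (0 where 3.38 are expected) lay further from chance and did not pass either (adjusted p = 0.500 for both).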
